A study of Mus musculus with 12 samples.

How the data were processed

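The series holds 12 RNA sequencing libraries of sorted CD4+ T cells from C57BL/6 mice in 4 groups of 3: total mRNA (input) and heavy polysome RNA (heavy), each with the label OA or 4E. Per the labels' protocols, mice were immunised with an alum adjuvant and then given vehicle or the eIF4E inhibitor 4EGI-1 by mouth, at 25 mg/kg each day for 7 days. By these protocols, cells were sorted on CD4 and CD45, polysomes were separated on sucrose gradients, and polyadenylated RNA went into a stranded library preparation. The labels never spell out OA or 4E. The columns of the authors' deposited comparison set an arm named OAE against OA. Here 4E was read as the inhibitor arm and OA as the vehicle arm, and each difference is 4E minus OA. Nothing says that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Libraries of light gradient fractions and of sorted T follicular helper (TFH) cells, which the protocols mention, were not analysed here.

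The authors deposited a table of whole-number read counts per gene symbol with 1 column per library, and 0 further columns belonged to other samples. Its name calls the values normalised, but they are whole numbers that sum to a different total in each library and include lines for reads in no gene and for ambiguous reads, so they were handled as raw counts and tested with the count model that the design provided for that case. Bowtie and the genome build mm9 are named in the submitters' processing notes, with no version or role; the counting tool and its annotation are not given in the sources used here. Gene symbols are in the human style although the samples are mouse, and 28 of them had been turned into calendar dates, of which 2 dates stand for 4 rows; these rows stayed in the tests and are never named. No coordinates are given, because no genome or annotation that matches this symbol set was at hand. Reads in no gene and ambiguous reads, 16.4% to 31.4% of the total per library, were left out of library sizes and tests. Ambiguous reads alone made up 0.384% to 1.91%. Near-identical gene copies, such as the MTRNR2L and histone genes, are uncertain, since the authors' counting may have split or dropped their shared reads.

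A second file is the authors' deposited table of their own comparison: log2 fold changes, p-values and adjusted p-values of 4E against OA for the transcriptome and the translatome, with a regulation class per gene. All of its classed genes have a p under 0.05 and an absolute log2 fold change above 1 in the fraction named. Its values were compared with those computed here and entered no test.

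Counts per library summed to between 691449 and 1906657 over 26485 gene rows, of which 12541 were at 0 in all libraries. The 7465 genes with at least 10 counts in at least 3 libraries were tested. Libraries were scaled by TMM factors (0.409 to 2.05), and levels are given as counts-per-million (CPM) after that scaling. A count of 0 allows a level of up to 3 counts, which is 0.781 to 6.82 CPM depending on the library; such floors cover counting error only. Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, glmQLFit and glmQLFTest) in 1 fit over all 12 libraries with 4 group means, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 5 contrasts were 4E minus OA in input, 4E minus OA in heavy, the interaction, and heavy minus input in each arm. The interaction is the change in heavy beyond that in input, which tests polysome association of a gene relative to the other genes. Standard errors of log2 changes came from the same fit.

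Gene lists were fixed before the data were examined: 29 lists with 755 symbols, of which 702 were in the table when case was ignored and 468 were tested. The 23 lists with at least 5 tested genes were tested two-sided with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. Th2, Th17, nuclear-retained and long noncoding RNA, plasma cell, CD8 T and NK cell, and erythroid and platelet lists had too few tested genes. Some listed symbols are mouse names, such as Hbb-bs in the erythroid list, while the table held the human-style HBB, which was tested. Too few tested genes in a list may thus reflect naming and not absent transcripts. Beside each list stands how many members passed when adjusted over all genes and when adjusted over the list alone. The list of eIF4E-sensitive mRNAs shares RRM2 and BIRC5 with proliferation, NFKBIA with immediate early and IRF7 with interferon genes, and the TFH list shares SLAMF6 with naive T cell and IRF4 with plasma cell genes. Single values per library (shares of reads) were compared with exact two-sided permutation tests, which with 3 against 3 libraries cannot give a p under 0.1.

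Genes to be named were chosen by a rule fixed before the data were examined: in each contrast, the genes of largest change among those that passed with a mean level at or above the median and no overlap between groups, or the 5 of smallest p in each direction where fewer than 5 passed; the 3 members of smallest p in each list that passed; up to 4 members of the TFH, eIF4E-sensitive and other-cell-type lists; and always Bcl6, Cxcr5, Pdcd1, Icos, Il21, Il4, Eif4e, Eif4g1, Eif4ebp1, Myc and Ccnd3 where measured. Genes outside the rule are said to have been chosen after their values were seen. Ranges over all alternatives are over those in which the gene or list was tested.

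The test was checked on simulated counts drawn from the means and library sizes of these libraries, with 200 of 7465 genes changed. Each gene had 1 mean over all libraries and was drawn independently. The simulation thus held no other difference between fractions, no outlying replicate, no pairing and no correlation between genes, and its shares may not carry over to the real libraries. At a log2 change of 1, 2 and 3 it recovered 13.4%, 49.3% and 83.3% of changed genes for 4E minus OA in input, 17.9%, 68.7% and 92.4% in heavy, and 2.99%, 32.8% and 66.7% for the interaction. For heavy minus input it recovered 8.96%, 61.2% and 83.3% in OA and 14.9%, 61.2% and 83.3% in 4E. Wrong calls among the unchanged genes made up 4.90% of calls in input, 9.16% in heavy, 11.7% in the interaction, 5.56% for heavy minus input in OA and 6.19% in 4E, so that with 1 simulation per comparison the share of false calls was above the threshold of 0.05 in all but input.

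Input and heavy libraries of an arm carry the same sample names (OA1-total with OA1, for example), but the labels do not say that they come from the same cells or animals. The deviations of same-named input and heavy libraries from their group means correlated at 0.669, 0.138 and 0.312 in OA. Libraries of different number also exceeded 0.1 there, with 0.227 for input replicate 2 with heavy replicate 3 and 0.163 for input replicate 3 with heavy replicate 2. Deviations in a group sum to 0, so the outlying replicate 1 draws replicates 2 and 3 together whatever their pairing. In OA only replicate 1 therefore speaks for pairing. In 4E same-named libraries correlated at 0.10, 0.0162 and 0.0475, and libraries of different number at -0.0721 to 0.0276. Each 4E input library correlated best with the heavy library of its name. Heavy replicate 2, however, correlated best with input replicate 3 (0.0276). All of these values are small, which leaves the pairing open. A fit with a block for each such pair was therefore set beside the interaction and the comparisons of heavy with input.

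Alternatives were no filter on low counts and a filter of 50 counts in 3 libraries, median-of-ratios scaling, quantile normalisation, a fit of only the groups compared, library weights, a robust estimate of the spread, DESeq2 1.42.0, the replicate number as a block (each same-named input and heavy pair for contrasts that compare fractions, and the number over all groups for contrasts between arms), an estimated correlation in camera, and each library left out in turn. After the data were seen, fits without OA replicate 1 in both fractions, without composition scaling, and with the level of COL1A1, HBB or MPO as a covariate were added.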

Results

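RNA sequencing was performed on CD4+ T cells of immunised mice that had received vehicle or 4EGI-1, a compound that keeps the cap-binding translation factor eIF4E from joining eIF4G. Each sample type was read as total mRNA (input) and as RNA from heavy polysomes, the part of a sucrose gradient in which transcripts loaded with many ribosomes sediment. The 12 libraries form 4 groups of 3: OA input, 4E input, OA heavy and 4E heavy. The labels do not spell out OA and 4E. The 4E libraries were read as the inhibitor arm, and directions are given as 4E relative to OA. The label of 4E heavy replicate 3 holds the word ReSubmission, and what was done again is not given in the sources used here. Reads counted in genes ranged from 691449 to 1906657 per library, and 8253 to 12185 gene rows held at least 1 read.

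Small noncoding RNAs (snoRNAs, scaRNAs, spliceosomal RNAs and the 7SL RNA of the signal recognition particle) took a large and uneven share of these reads. This class was chosen after its values were seen. The protocols describe libraries of polyadenylated RNA. How this class came to hold so many reads was not tested, so input is total mRNA by its label only. They made up 59.8% ± 22.8 of gene reads in OA input and 76.6% ± 1.58 in 4E input (SD, n = 3), against 8.29% ± 4.61 in OA heavy and 14.0% ± 3.18 in 4E heavy. The 7SL gene RN7SL1 alone held 49.8% ± 23.2 of gene reads in OA input and 62.7% ± 3.38 in 4E input. OA replicate 1 stood apart from the other libraries of its arm, with 33.6% small noncoding RNA in input, where replicates 2 and 3 had 74.9% and 71%, and 3.14% in heavy, where they had 9.70% and 12%. Outside this class OA input replicate 1 kept 1258673 reads, the other OA input libraries 324535 and 305469, and the 4E input libraries 234469 to 250238. The difference between arms gave an exact two-sided permutation p of 0.1 in input and 0.2 in heavy (n = 3 per group), and 0.1 is the smallest p that this design allows. Spearman correlations over the tested genes were 0.840 to 0.943 within groups and 0.791 to 0.962 between groups, and the first principal component held 27% of the variance. The value of 0.962 joined OA input replicate 1 to OA heavy replicate 1. That input library correlated at only 0.840 and 0.863 with OA input replicates 2 and 3. On the first component it lay at -38.6, with OA heavy replicate 1 at -54.5 and the other input libraries at 12.1 to 52.1.

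**Figure D1:**
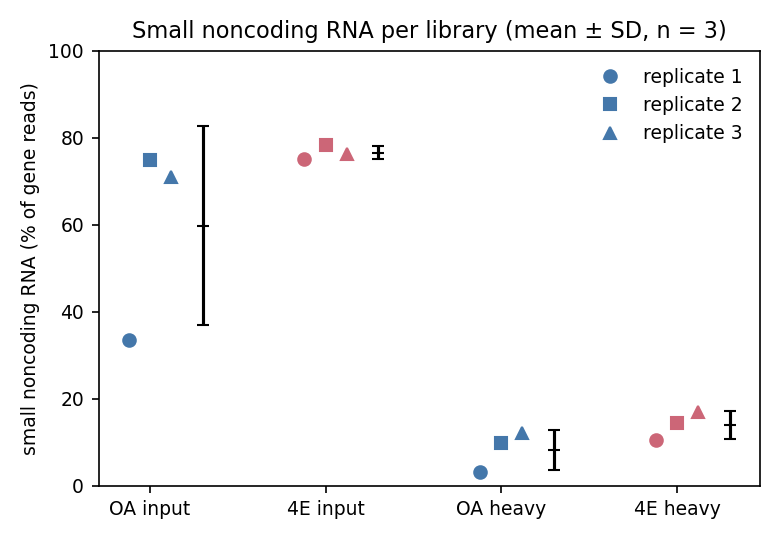
Share of gene reads from small noncoding RNA genes, in percent, for each of the 12 libraries, with marker shapes for the replicate, colours for the arm, and black marks for the mean ± SD of each group. Input libraries lie between 33.6% and 78.3% and heavy polysome libraries between 3.14% and 16.9%, with OA replicate 1 the lowest in each fraction.

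T cell transcripts were present, some of them at very low counts. The 12 libraries together held 8791 counts of PTPRC (CD45), 5355 of the T cell kinase LCK, 935 of the receptor chain CD3E and 100 of CD4. CD3D and the cytokine gene IL4 had 0 counts in all 12 libraries, which allows up to 0.219 CPM of all gene reads. Among the genes of TFH cells and of the drug target, PDCD1 (9 counts), ICOS (20), IL21 (7), EIF4E (49) and EIF4EBP1 (21) stayed under the count minimum and were not tested. Symbols in the table are human in style, and 6856 of 7450 tested symbols matched a mouse symbol when case was ignored. Levels are therefore compared between libraries for each gene and not between genes.

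Total mRNA was compared between arms to ask which transcripts differed in level. Genes of cell division were lower in 4E as a group: 25 of 27 tested proliferation genes had a lower level, with a median log2 change of -0.80 (camera adjusted p = 4.4e-07, and adjusted p = 0.163 with an estimated correlation). In mean level of the list, each 4E input library lay below each OA input library. TOP2A, which untangles replicated chromosomes, stood at 65.1 ± 31.6 CPM in OA and 14.8 ± 1.38 CPM in 4E (SD, n = 3, log2 change -2.14, SE 0.54). The replicative helicase subunit MCM5 had a log2 change of -1.58 (SE 0.42) and KIF23, a kinesin of cytokinesis, one of -3.25 (SE 0.93). No proliferation gene passed when adjusted over all genes, and 3 fell when adjusted over the list alone.

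Stromal and endothelial markers were also lower in 4E input: 4 of 5 tested genes, median log2 change -2.28 (camera adjusted p = 7.3e-04, and adjusted p = 0.163 with an estimated correlation), with 0 passing over all genes and 3 falling when adjusted over the list alone. The fibrillar collagen gene COL1A1 measured 138 ± 135 CPM in OA and 27.3 ± 0.879 CPM in 4E (SD, n = 3, log2 change -2.28, SE 0.76), and COL3A1 62.9 ± 55.4 and 1.45 ± 2.51 CPM (-5.25, SE 1.20). The COL3A1 mean in 4E lies below the floor of those libraries (6.52 to 6.82 CPM), so the size of its fall is uncertain. The OA libraries were unequal, with COL1A1 at 27.7, 99.3 and 288 CPM in OA input replicates 1, 2 and 3. The haemoglobin gene HBB, chosen after its values were seen, was also lowest in replicate 1, at 60.6, 319 and 331 CPM. Without OA replicate 1 in both fractions, a choice made after the data were seen, COL1A1 (adjusted p = 2.4e-05) and COL3A1 (1.8e-05) fell in edgeR. Leaving out the OA library with the lowest collagen level favours such a call. Over all alternatives their adjusted p ranged from 3.3e-08 to 0.627 and from 5.2e-11 to 0.607.

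Proteasome genes were lower in 4E input in 26 of 33 cases, with a median log2 change of -0.49 (camera adjusted p = 0.0230, and adjusted p = 0.717 with an estimated correlation) and 0 members passing either over all genes or when adjusted over the list alone. PSMB4 (-1.75, SE 0.53) and PSMA1 (-2.03, SE 0.70), subunits of the catalytic core, had the smallest p. That list no longer passed without OA input replicate 1 (median log2 change -0.14, adjusted p = 0.497), whose proteasome level was the highest of the 6 input libraries, or without 4E input replicate 2 (-0.43, 0.0921). Over all alternatives the median ranged from -1.48 to -0.14 and the adjusted p of the list from 0.00498 to 0.717.

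The TFH programme had 10 of 14 tested genes lower in 4E input and did not pass (median log2 change -0.70, camera adjusted p = 0.160, with 0 passing over all genes or adjusted over the list alone). CXCR5, the receptor that takes TFH cells to follicles, measured 10.9 ± 4.82 CPM in OA and 3.0 ± 3.48 CPM in 4E (SD, n = 3). The 4E value rests on 4 counts in all and lies below the floor of those libraries (6.52 to 6.82 CPM). BCL6, the transcription factor that specifies TFH cells, measured 80.4 ± 13.8 and 57.1 ± 13.7 CPM (SD, n = 3). OA input replicate 1 had the highest mean level of the list among the 6 input libraries. Without OA input replicate 2 the list passed (adjusted p = 0.0475), and over all alternatives its adjusted p was 0.0306 to 0.717 and its median -1.75 to -0.13. Transcripts known to depend on eIF4E for translation were divided evenly, with 10 of 20 higher and 10 lower (median log2 change -0.0097, mean 0.034, adjusted p = 0.611, with 0 passing over all genes or adjusted over the list alone). Among them VEGFA had a log2 change of 0.90 (SE 0.38) and XIAP, an inhibitor of apoptosis, one of -1.13 (SE 0.55).

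Other preset lists did not pass in input. Small noncoding RNAs, the class chosen after its values were seen, were higher in 4E input in 59 of 65 cases, with a median log2 change of 1.55 (camera, p = 0.0209 with an estimated correlation, not adjusted for the classes tried) and of 0.93 without composition scaling. In 4E heavy 43 of 65 were higher (median 0.37, camera p = 0.481 with an estimated correlation), and 32 of 65 without OA replicate 1 (median 0). Adjusted p of the other preset lists in input was 0.0726 for other 5′ TOP mRNAs, 0.104 for oxidative phosphorylation and for B cell markers, and 0.160 for naive T cell, myeloid, unfolded protein response and mTORC1 genes. It was 0.563 for ribosomal proteins, Th1, immediate early and glycolysis genes. It was 0.611 for T cell receptor signalling and cholesterol synthesis, 0.684 for the ATF4 stress response, 0.843 for translation initiation factors and heat shock, 0.932 for regulatory T cell and 0.941 for interferon response genes. The ribosomal protein list took opposite directions with libraries left out, passing as higher in 4E without OA input replicate 1 (adjusted p = 0.0291) and as lower without OA input replicate 2 (0.0346). Naive T cell genes passed as higher without OA input replicate 1 (0.0218), and without OA replicate 1 in both fractions naive T cell (0.00729) and ribosomal protein (0.0174) genes both passed as higher. Other 5′ TOP mRNAs passed as lower without OA input replicates 2 (0.00498) or 3 (0.0490) or 4E input replicate 1 (0.0184), oxidative phosphorylation as lower without OA input replicate 2 (0.0257), and B cell markers as higher without OA input replicate 3 (0.0402) or 4E input replicate 1 (0.0184). With all libraries, other 5′ TOP mRNAs passed as lower with no filter (camera adjusted p = 0.0458) or a filter of 50 counts (0.0251). They also did so with quantile normalisation (0.0412) and without composition scaling (0.0253).

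Among single genes in input, edgeR called 0 of 7465 at an adjusted p under 0.05, 786 had an unadjusted p under 0.05, and DESeq2 called 3, all higher in 4E. These were ZBTB16, the transcription factor PLZF of innate-like T cells, the Cajal body RNA SCARNA8 and the snoRNA SNORD94. ZBTB16 measured 47.7 ± 12.8 CPM in OA and 135 ± 9.43 CPM in 4E (SD, n = 3, log2 change 1.54, SE 0.29, edgeR adjusted p = 0.209), and SNORD94 487 ± 136 and 1204 ± 179 CPM (1.31, SE 0.28, 0.250). The lowest p among genes lower in 4E belonged to MTHFD1, an enzyme of one-carbon folate metabolism, at 24.7 ± 13.6 and 2.25 ± 2.27 CPM (-3.41, SE 0.73, 0.250). Its 4E mean lies below the floor of those libraries (6.52 to 6.82 CPM), so the size of the fall is uncertain. EEF2K, the kinase that inactivates elongation factor 2, had a log2 change of -3.76 (SE 0.90, 0.32), and the chaperonin subunit CCT6A one of -1.37 (SE 0.32, 0.32). EIF4G1, the scaffold that eIF4E binds, stood at 410 ± 30.8 and 415 ± 13.9 CPM (log2 change 0.02, SE 0.19, 0.977). Without OA input replicate 3, 14 genes passed, among them ZBTB16 (adjusted p = 0.0399), SNORD94 (0.0413) and MTHFD1 (0.0413), whose ranges over all alternatives were 5.0e-04 to 0.520, 8.9e-05 to 0.520 and 0.00252 to 0.520. The count was 26 without OA replicate 1 in both fractions. The count of lists was 3 with all libraries, 7 without OA input replicate 2, and 5 without OA input replicate 3 or 4E input replicate 1.

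**Figure D2:**
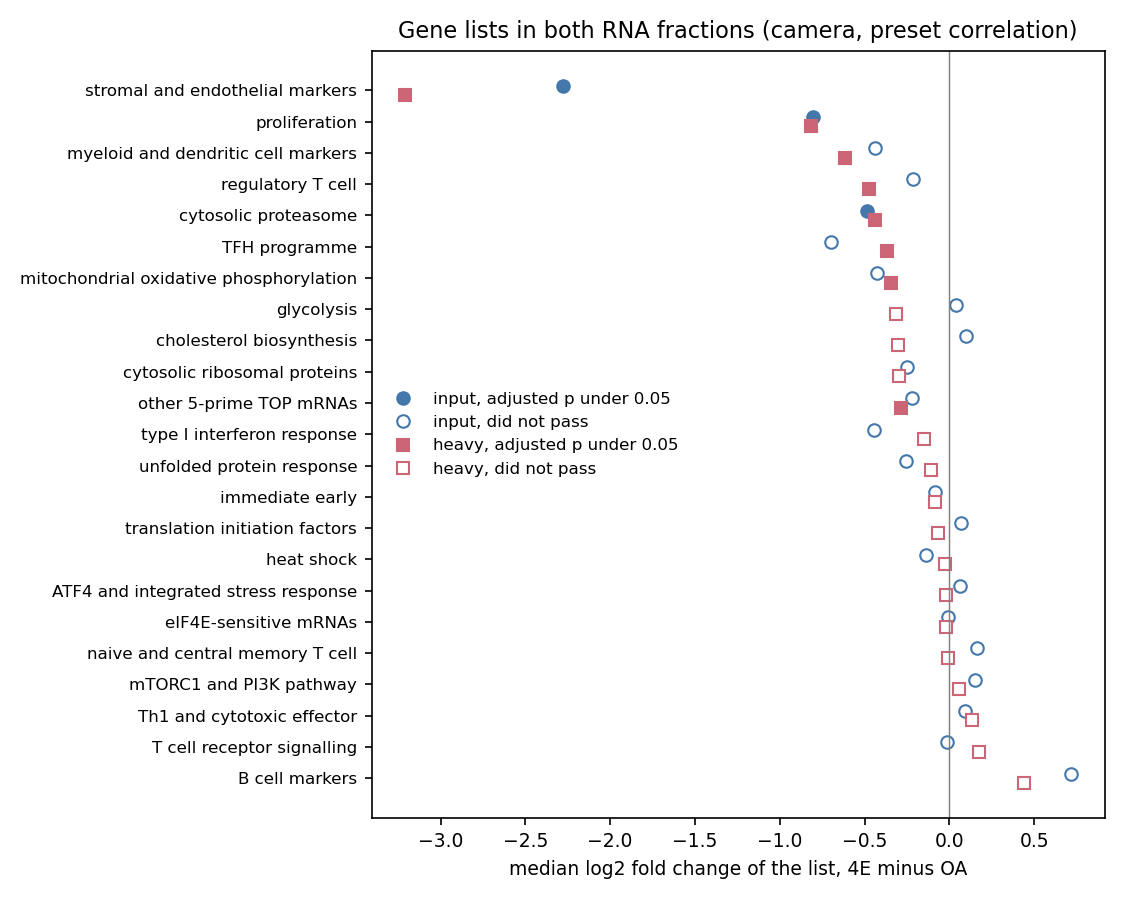
Median log2 fold change, 4E minus OA, of the 23 tested gene lists in input (circles) and heavy polysome RNA (squares), 3 libraries per group; filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation. Filled symbols number 3 in input and 8 in heavy, all to the left of 0, with stromal markers at -2.28 and -3.21 and proliferation genes at -0.80 and -0.81.

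Heavy polysome RNA was compared in the same way, to ask which transcripts differed among those being translated by many ribosomes. Proliferation genes were lower in 4E in 26 of 27 cases, with a median log2 change of -0.81 (camera adjusted p = 1.6e-12, and adjusted p = 0.0482 with an estimated correlation). Of these 0 passed over all genes and 7 fell when adjusted over the list alone. TOP2A stood at 50.9 ± 20.6 CPM in OA and 12.1 ± 9.72 CPM in 4E (SD, n = 3, log2 change -2.15, SE 0.48), and the helicase subunit MCM6 at 103 ± 20.7 and 53.9 ± 6.16 CPM (-0.93, SE 0.24). Cyclin A2 (CCNA2) had a log2 change of -3.41 (SE 0.94). Each OA heavy library lay above each 4E heavy library in the mean level of the list. Stromal markers were lower in 4 of 5 cases (median -3.21, camera adjusted p = 1.1e-04, and adjusted p = 0.0482 with an estimated correlation, with 0 passing over all genes and 3 falling when adjusted over the list alone). The median of this list was -1.02 with no filter on low counts and ranged from -3.75 to -1.02 over the 16 alternatives that tested it, in which it passed. With a filter of 50 counts too few of its genes were left for a test. COL1A1 measured 121 ± 105 CPM in OA and 11.8 ± 2.17 CPM in 4E (-3.35, SE 0.73). In OA heavy replicates 1, 2 and 3 it stood at 24.7, 106 and 233 CPM, where HBB, chosen after its values were seen, stood at 44.3, 474 and 207 CPM.

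Myeloid markers were lower in 4E heavy in 4 of 5 cases (median log2 change -0.62, camera adjusted p = 0.00795, and adjusted p = 0.329 with an estimated correlation, with 0 passing over all genes and 1 falling when adjusted over the list alone). MPO, the myeloperoxidase of granulocyte precursors, measured 26.3 ± 11.5 CPM in OA and 1.61 ± 1.82 CPM in 4E (SD, n = 3, log2 change -4.13, SE 0.79, edgeR adjusted p = 0.182), and SPI1, the myeloid transcription factor PU.1, had a log2 change of -2.02 (SE 0.83). The MPO mean in 4E lies below the floor of those libraries (1.87 to 2.69 CPM), so the size of its fall is uncertain. Without 4E heavy replicate 1 this list did not pass (median -0.42, adjusted p = 0.102). Over the 16 alternatives that tested it the median was -0.93 to -0.15 and the adjusted p 0.0024 to 0.349.

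Of the lists of CD4 T cell subsets tested in heavy polysomes, the TFH and regulatory T cell lists passed and the Th1 and naive T cell lists did not, though no test compared the subsets with one another. The TFH programme was lower in 12 of 14 tested genes (median log2 change -0.37, camera adjusted p = 0.0241, and adjusted p = 0.348 with an estimated correlation, with 0 passing over all genes or adjusted over the list alone). TOX2, a TFH transcription factor, stood at 24.7 ± 0.949 CPM in OA and 7.71 ± 3.74 CPM in 4E (SD, n = 3, -1.64, SE 0.56), and BCL6 at 82.8 ± 8.55 and 54.5 ± 8.81 CPM (-0.61, SE 0.24). Regulatory T cell genes were lower in 7 of 9 cases (median -0.47, camera adjusted p = 0.0436, and adjusted p = 0.427 with an estimated correlation, with 0 passing over all genes and 2 falling when adjusted over the list alone), among them the inhibitory receptor CTLA4 (-1.06, SE 0.37) and the transcription factor IKZF4 (-1.35, SE 0.47). OA heavy replicate 1 had the highest mean level of the TFH list, and without it neither list passed, with medians of -0.23 for TFH (adjusted p = 0.0879) and -0.20 for regulatory T cell genes (0.381). Neither passed without 4E heavy replicate 1, where the TFH median was larger than with all libraries (-0.56, adjusted p = 0.102) and that of regulatory T cell genes was -0.35 (0.0556). Regulatory T cell genes did not pass without 4E heavy replicate 3 either (-0.43, 0.141). Over all alternatives the medians were -0.64 to -0.23 and -0.66 to -0.20, and the adjusted p 0.0142 to 0.348 and 0.0142 to 0.427.

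The lists of other 5′ TOP mRNAs, oxidative phosphorylation and the proteasome passed in heavy polysomes, while ribosomal proteins and translation initiation factors did not. No test compared these lists with one another, so this does not show that they behaved differently. Other 5′ TOP mRNAs, a list of translation factors and of other genes such as VIM and HNRNPA1, were lower in 13 of 15 cases (median log2 change -0.28, camera adjusted p = 0.0466, and adjusted p = 0.486 with an estimated correlation), with the elongation factor subunit EEF1B2 at -1.71 (SE 0.51) and the initiation factor subunit EIF3E at -0.74 (SE 0.43). Oxidative phosphorylation genes were lower in 30 of 42 cases (median -0.34, camera adjusted p = 0.00795, and adjusted p = 0.427 with an estimated correlation), with the cytochrome oxidase subunits COX5A at -1.76 (SE 0.57) and COX5B at -1.17 (SE 0.49). Proteasome genes were lower in 26 of 33 cases (median -0.44, camera adjusted p = 0.0240, and adjusted p = 0.486 with an estimated correlation), with PSMA2 at -1.37 (SE 0.52). In each of these 3 lists 0 genes passed over all genes or when adjusted over the list alone. Without OA heavy replicate 1 the median was -0.18 for 5′ TOP mRNAs (adjusted p = 0.228), -0.21 for oxidative phosphorylation (0.0879) and near 0 for proteasome genes (-0.033, 0.410). That library had the highest mean level of the oxidative phosphorylation and proteasome lists. The 5′ TOP list also failed to pass without 4E heavy replicates 1 (a larger median of -0.40, adjusted p = 0.0783), 2 (-0.21, 0.0690) or 3 (-0.19, 0.117), and the proteasome list without 4E heavy replicate 3 (-0.13, 0.113). Over all alternatives the medians of the 3 lists were -0.51 to -0.18, -0.53 to -0.21 and -0.63 to -0.033, and the adjusted p 0.0149 to 0.486, 0.00177 to 0.427 and 0.00467 to 0.486.

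Transcripts known to depend on eIF4E were again divided in heavy polysomes, with 11 of 20 lower (median log2 change -0.02, camera adjusted p = 0.878, with 0 passing over all genes or adjusted over the list alone). VEGFA had a log2 change of 0.91 (SE 0.34), the cell cycle kinase CDK4 one of -1.37 (SE 0.53), MYC one of 0.23 (SE 0.32) and CCND3, cyclin D3, one of -0.27 (SE 0.23). The other lists did not pass. Adjusted p was 0.183 for T cell receptor signalling, 0.192 for ribosomal proteins, unfolded protein response and glycolysis, 0.202 for B cell markers, and 0.262 for immediate early genes. It was 0.343 for interferon response and cholesterol synthesis, 0.360 for naive T cell and Th1 genes, 0.429 for translation initiation factors, 0.659 for the ATF4 stress response and mTORC1 genes, and 0.677 for heat shock. With libraries left out, ribosomal proteins passed as lower without OA heavy replicates 2 (0.0368) or 3 (0.0101), T cell receptor genes as higher without OA heavy replicate 1 (0.0224), and B cell markers as higher without OA heavy replicate 3 (0.0142) or 4E heavy replicate 1 (0.00688).

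Of single genes in heavy polysomes, edgeR called 0 of 7465, 613 had an unadjusted p under 0.05, and DESeq2 called 1, MPO. Among genes higher in 4E the smallest p belonged to ACTR1B, a dynactin subunit, at 54.0 ± 8.82 CPM in OA and 108 ± 19.4 CPM in 4E (SD, n = 3, log2 change 1.0, SE 0.23, edgeR adjusted p = 0.422). GFI1, a transcriptional repressor of blood cells, had a log2 change of 1.21 (SE 0.33, 0.569). Leaving out OA heavy replicate 1 gave 3 called genes, all collagens and all lower: COL1A1 (adjusted p = 0.00379), COL1A2 (0.0413) and COL3A1 (0.00210). Over all alternatives their adjusted p ranged from 9.6e-20, 7.7e-13 and 1.8e-16 to 0.903. Without OA replicate 1 in both fractions 9 genes passed, all lower in 4E. The count of lists was 8 with all libraries, 4 without OA heavy replicate 1, and 5 without 4E heavy replicate 1 or 3.

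**Figure D3:**
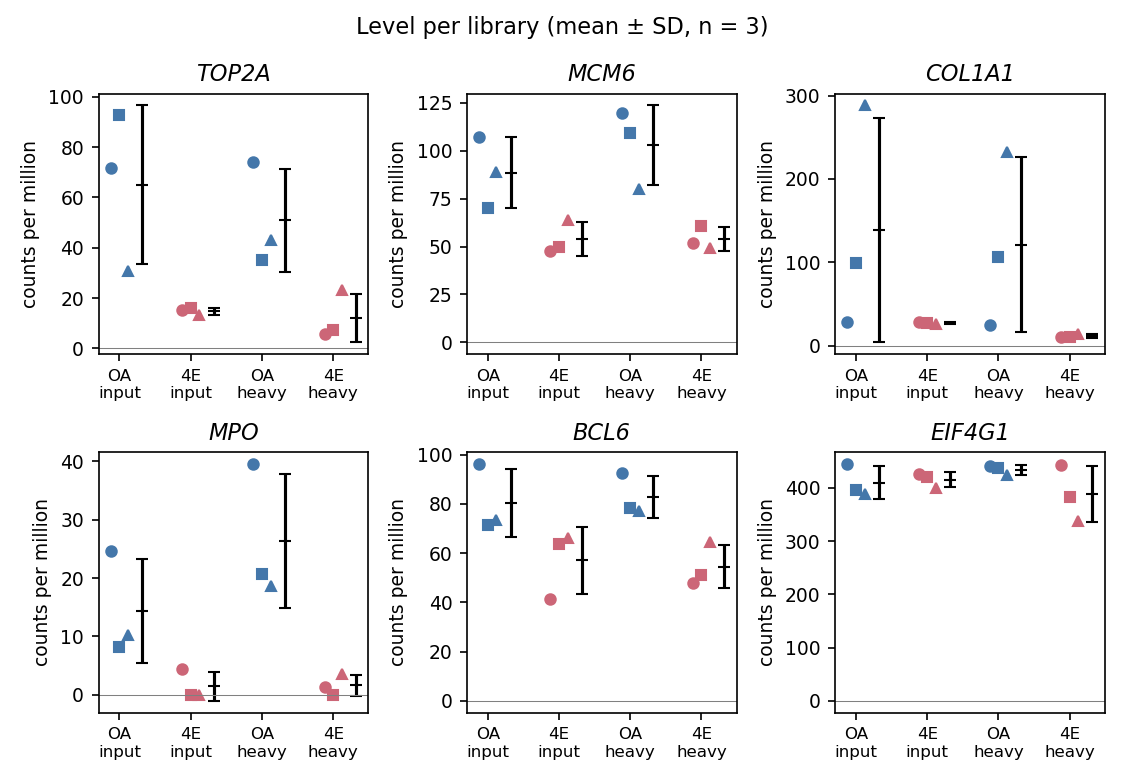
Levels in CPM of 6 genes in each library, with shapes for replicates, colours for the arm and black marks for mean ± SD (n = 3). TOP2A, MCM6 and MPO lie lower in the 4E libraries of each fraction, COL1A1 varies from 24.7 to 288 CPM between OA libraries, and EIF4G1 has group means between 388 and 434 CPM.

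The interaction asked whether polysome association changed beyond total mRNA, the comparison closest to translational regulation. Scaling by TMM centres each comparison near its typical gene, with a median log2 change of 0.0496 here and -0.0023 in heavy. Camera sets each list against the other genes. A change in polysome loading shared by all genes could therefore not appear, and the results do not bear on it. In edgeR 0 of 7465 genes passed (smallest adjusted p 1.0), 159 had an unadjusted p under 0.05, and DESeq2 called 0. Those 159 are a smaller share of the tested genes than the 0.05 that chance alone would give. The fit without pairs may thus be too strict for this contrast, and its count of 0 does not show that nothing changed. With a block for each input and heavy library of the same name, 10 genes passed, 1 higher and 9 lower, and 0 lists. Without the block 0 of 23 lists passed (smallest adjusted p 0.134, for regulatory T cell and glycolysis genes). BCL6 had an interaction of -0.10 (SE 0.36), CXCR5 one of 1.02 (SE 1.01), MYC one of -0.30 (SE 0.46) and EIF4G1 one of -0.18 (SE 0.26). The interactions of BCL6, MYC and EIF4G1 were 0.66, 0.16 and 0.54 without composition scaling, which moved the median of all genes by 0.68. Adjusted p was 0.802 for eIF4E-sensitive mRNAs and for ribosomal proteins and 0.854 for the TFH programme. Of the genes with the smallest p, UBA6, a ubiquitin-activating enzyme, had an interaction of 2.19 (SE 0.69) and IP6K1, an inositol hexakisphosphate kinase, one of -0.86 (SE 0.31), each with an adjusted p of 1.0. No gene could be placed in a class of regulation in transcription or translation alone, since 0 passed in either fraction. Regulatory T cell (adjusted p = 0.0195), glycolysis (0.0416) and ribosomal protein (5.3e-04) genes passed as lower without OA input replicate 1, and regulatory T cell and glycolysis genes (0.0296 each) without OA heavy replicate 3, and simulated changes of 1 on the log2 scale were recovered in 2.99% of genes.

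Heavy polysomes were then compared with input inside each arm. In OA 51 genes were lower in heavy polysomes and 0 higher (163 at an unadjusted p under 0.05), and in 4E 70 were lower and 0 higher (417). The 163 in OA are also a smaller share of the tested genes than 0.05. DESeq2 called 58 and 76, all lower. With a block for each input and heavy library of the same name, 90 genes passed in OA, 6 higher and 84 lower, and 109 in 4E, 13 higher and 96 lower, among which were all 51 and all 70. Small noncoding RNAs, which are not translated, made up 44 of the 51 and 59 of the 70, out of 65 tested (Fisher's exact p = 8.0e-92 and 9.6e-129). Fisher's test takes the genes as independent, while the estimated correlation within this class, chosen after its values were seen, was 0.457 in OA and 0.511 in 4E. Camera with that correlation gave p = 2.9e-05 and 2.6e-05. The median log2 change of the class was -3.41 in OA and -4.58 in 4E, and without composition scaling -1.95 and -2.64. That setting called 3006 genes higher and 48 lower in OA and 5978 higher and 57 lower in 4E. The snoRNA SNORA81 fell by 6.14 on the log2 scale (SE 0.40, edgeR adjusted p = 3.2e-08) in OA and fell by 5.75 (SE 0.38, 4.1e-08) in 4E. The minor spliceosome RNA RNU11 fell by 5.87 in 4E (SE 0.71, 5.5e-05). RN7SL1 fell by 5.04 in OA (SE 0.85, 0.00305), but did not pass with a filter of 50 counts (0.0677) or a fit of only the groups compared (0.241), and quantile normalisation, which ties it as the gene of highest count, set its change to 0 (range over all alternatives 5.6e-34 to 1.0). Both arms shared 48 of these genes, where independent lists drawn from all tested genes would share 0.478. Most of both lists came from the same 65 small noncoding rows. The overlap thus restates that class and does not show agreement between arms gene by gene.

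Outside this class the falls in OA were 6 MTRNR2L genes, near copies of a mitochondrial ribosomal RNA segment, and RNVU1-8, a variant of the U1 spliceosomal RNA that the class does not hold, all chosen after their values were seen. In 4E they were 5 MTRNR2L genes and 6 others, among them the ribosomal protein genes RPS3 (-1.52, SE 0.23, edgeR adjusted p = 7.0e-04) and RPLP1 (-1.51, SE 0.29, 0.00714) and the chaperone gene DNAJA1 (-1.33, SE 0.26, 0.00805), also chosen after their values were seen. These last 3 had log2 changes of 0.42, 0.43 and 0.62 without composition scaling, which moved the median of all genes by 1.93, and none of them passed there (0.233, 0.398 and 0.0743). RPLP1 did not pass without 4E input replicate 3 (0.0690) or 4E heavy replicate 2 (0.0590). DNAJA1 did not pass without 4E input replicate 2 (0.0654) or 4E heavy replicates 1 (0.0610), 2 (0.0529) or 3 (0.0778). Over all alternatives the ranges were 4.8e-17 to 0.233 for RPS3, 3.3e-07 to 0.398 for RPLP1 and 1.9e-13 to 0.0778 for DNAJA1. No list passed in either arm (camera, 0 of 23, with a smallest adjusted p of 0.221 in OA and 0.166 in 4E). In OA ribosomal protein genes passed as lower without input replicates 2 (2.5e-05) or 3 (0.00281) or heavy replicate 1 (1.5e-06), and other 5′ TOP mRNAs without input replicate 2 (0.0384). In 4E heat shock genes passed as lower without input replicate 3 (0.0244) or heavy replicate 1 (0.0457), and ribosomal protein genes without heavy replicate 1 (0.0457).

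In the authors' deposited table of 11228 rows, 0 genes had an adjusted p under 0.05 for total mRNA and 10 for heavy polysomes, 9 lower and 1 higher in 4E. None of these 10 passed the count minimum used here, and the highest count of any of them in a library was 15. An unadjusted p under 0.05 was given to 906 rows in total mRNA and 840 in heavy polysomes. The authors' deposited table placed 641 rows in a class of transcription alone, 667 in translation alone, 64 in both and 19 in opposite directions. Each of these had that p and an absolute log2 change above 1 in the fraction named, but of 1411 rows with such values in a fraction 20 were given no class. Across 7450 genes, which are not independent replicates, log2 changes in the authors' deposited table correlated with those computed here with Pearson r of 0.875 in input and 0.959 in heavy, and 91.9% and 95.5% of genes had the same sign.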

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

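The tests on gene symbols and on an exchange of OA replicate 1 libraries were chosen after the result was seen, as was the comparison of reads in no gene, and the fits with a marker level or without OA replicate 1 were added after the data were seen.

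Reads assigned to no gene, which the comparisons above do not use, made up 25.1% ± 1.39 of reads in 4E input (24.9%, 23.8% and 26.6%) and 18.9% ± 0.192 in OA input (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible), so every 4E input library lay above every OA input library. In heavy polysomes the values were 26.8% ± 5.08 and 22.3% ± 7.51 (exact p = 0.4).

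The symbols of the table are human in style, while the samples are labelled mouse and the processing notes name a mouse build. Human cells are argued against by 7 human genes with no mouse gene of that name (IL32, CD58, GNLY, GZMH, APOBEC3C, APOBEC3G and CXCL8), which summed to 0 counts over 12 libraries. A plain renaming of mouse genes is argued against by 30 tested genes with LINC, LOC, antisense or MTRNR2L names, which stand for human transcripts. Mouse reads counted against a human annotation, so that only well-conserved stretches are counted, may account for near-empty genes such as CD3D; the CD3 chain, CD4 and B2M rows together held 132 reads-per-million, between the values set for and against this, and no human genome was used here to settle it. No biological explanation was tested.

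OA replicate 1 stood apart in both fractions, with less small noncoding RNA and more genes detected. Depth alone is argued against: drawn down to the 234469 reads of the smallest library outside small noncoding RNA, OA input replicate 1 still held 9425 gene rows, above the 8147 to 9029 of the other 5 input libraries by more than their SD of 361, though by a small margin, and in heavy polysomes it held 9544 against 8460 to 9286 (SD 350), a gap below that SD. A full exchange of its input and heavy libraries is argued against by the 3.14% of small noncoding RNA in the library labelled heavy, against 33.6% in the one labelled input. These shares do not bear on a partial mixing of those libraries, which was not tested. A difference in RNA yield, library preparation or the mice themselves stays open and was not tested.

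Lower proliferation genes in the 4E arm are the pattern with the smallest list p. RNA of stromal, red blood or myeloid cells, most of which a sort on CD4 and CD45 would remove, could not be excluded as a cause. With the level of COL1A1, HBB or MPO in the model the median log2 change in heavy polysomes was -0.91, -0.67 or -1.05. The list passed each time (camera at the preset correlation, adjusted p at most 8.2e-04), and no estimated correlation was tried there. Each marker is a single gene that was itself lower in 4E heavy, so such a fit cannot fully separate its level from the arm. OA replicate 1 as the cause is argued against by medians of -0.78 in input and -0.87 in heavy without it. A difference between the arms in the cells themselves stays open and was not tested.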

How the results depend on the processing

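The fits without OA replicate 1 in both fractions, without composition scaling and with a marker level in the model were chosen after the data were seen, as were list tests under settings other than an estimated correlation, median of ratios, quantile normalisation, the replicate block and left-out libraries. The 7465-gene filter and shallow input libraries limit what can be called. The pseudocount alternative was not run, since the count model has none, and a fit of only the groups compared has no interaction.

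Median-of-ratios scaling moved no count of genes by over 1.5 times. Genes called in input, heavy and the interaction were 113, 50 and 4 with no filter, 3, 1 and 0 with DESeq2, 1, 0 and 0 with library weights, 1, 1 and 0 without composition scaling, and 26, 9 and 0 without OA replicate 1. For OA heavy minus input, where 51 were called, the count was 80 with no filter, 32 with a filter of 50, 12 with only the groups compared and 17 with a robust spread. For 4E heavy minus input, where 70 were called, it was 43 with a filter of 50 and 42 with a robust spread. Without composition scaling these counts were 3054 (3006 higher, 48 lower) and 6035 (5978 higher, 57 lower), because that setting moved the median of all genes by 1.24 in OA and 1.93 in 4E, and by -0.88 in input, -0.18 in heavy and 0.68 in the interaction. Genes called in either 4E against OA contrast numbered 27 without OA replicate 1 and 0 at an adjusted p under 0.1.

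Not every OA input library correlated best with the heavy library of its name, since replicate 2 correlated at 0.227 with heavy replicate 3. Between the arms, libraries of the same number correlated at 0.109, 0.0593 and 0.0425 in input and 0.279, 0.0152 and 0.147 in heavy. These values leave open whether a replicate number marks anything shared between the arms. With the replicate block the counts of genes were 71 (50 higher, 21 lower), 27 (14 higher, 13 lower), 10, 90 and 109 for input, heavy, the interaction, OA and 4E heavy against input, and 5 lists passed in input, B cell markers higher and other 5′ TOP mRNAs lower among them, and ribosomal proteins also passed as lower in heavy. The block changed no call of a list or a named gene in the interaction or in heavy against input.

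Lists that passed in input, 3 with the planned settings, were 5 with no filter, 0 with an estimated correlation and 6 without composition scaling. Without OA replicate 1 they were 4, with naive T cell and ribosomal protein genes higher in 4E. In heavy, where 8 passed, they were 4 with no filter, 5 with a filter of 50, 5 with library weights, 2 with an estimated correlation and 5 without OA replicate 1 (2 of them higher in 4E, naive T cell and T cell receptor genes). Quantile normalisation also gave 8 in heavy, but not the same ones. Regulatory T cell and myeloid lists no longer passed (camera adjusted p = 0.0664 each). Unfolded protein response (0.0410) and immediate early (0.0173) genes passed there as lower. In the interaction 1 passed with a filter of 50; for heavy against input in OA 1 each with quantile normalisation and without composition scaling; and in 4E 1 with library weights. The cause of these changes was not tested.

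With 1 library left out, called genes ranged from 0 to 14 in input, 0 to 3 in heavy, 0 to 0 in the interaction, 35 to 68 in OA and 47 to 62 in 4E heavy against input, and 0 to 14 in either 4E against OA contrast (14, 4 and 7 without OA input replicates 3 and 1 and OA heavy replicate 1). Lists ranged from 2 to 7 in input, 4 to 10 in heavy, 0 to 3 in the interaction and 0 to 2 in each arm of heavy against input. Without 1 library an arm of 2 is assumed to vary like the other groups.

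Some values changed sign, among them DNAJA1, RPS3 and RPLP1, which had passed. EIF4G1 in input was -0.039 with no filter, -0.021 with a filter of 50, -0.14 with quantile normalisation, -0.00071 with DESeq2, -0.88 without composition scaling and -0.020 to 0.068 over left-out libraries. Without composition scaling CCND2, XBP1 and MYC in input were -0.37, -0.088 and -0.10, BCL6, EIF4G1 and MYC in the interaction 0.66, 0.54 and 0.16, and DNAJA1, RPS3 and RPLP1 in 4E heavy against input 0.62, 0.42 and 0.43. MYC in heavy was -0.015 without OA replicate 1 and -0.035 to 0.45 over left-out libraries; interactions ranged from -0.29 to 0.024 for BCL6 and -0.61 to 0.046 for MYC. The median of eIF4E-sensitive mRNAs was 0.055 with a filter of 50, 0.063 with library weights and 0.038 without OA replicate 1 in input (-0.035 to 0.071 over left-out libraries), 0.025 with a filter of 50 in heavy (-0.045 to 0.024), and 0.66 without composition scaling in the interaction (-0.10 to 0.034). In all, 11 of 115 gene results and 3 of 15 list results changed sign under some alternative, and 4 and 3 did so under an alternative other than no composition scaling; 1881 of the gene values under alternatives kept their direction and side of the threshold, 94 came to pass, 13 ceased to pass without a change of sign, and 21 changed sign, among which DNAJA1, RPS3 and RPLP1 ceased to pass as well.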

Other observations

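The classes of histone and MTRNR2L genes and the red blood cell genes were chosen after their values were seen, and the counts of splits were planned.

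In heavy polysomes 32 of 36 tested histone genes were lower in 4E (median log2 change -0.74; camera p = 0.0267 with an estimated correlation, not adjusted for the classes tried), and in input 31 of 36 were lower (median -0.58; p = 0.0864 with an estimated correlation). None of the 36 passed in either fraction when adjusted over all genes. The median in heavy was -0.78 with median-of-ratios scaling, -0.79 with quantile normalisation, -0.94 without composition scaling and -0.58 without OA replicate 1.

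The red blood cell genes ANK1, SPTB and HBB were lowest in replicate 1 among the OA libraries of each fraction, while ITGA2B, the 1 tested gene of the fixed list of erythroid and platelet markers, was not in input (13.9, 16.3 and 11.9 CPM). ANK1, which anchors the red cell membrane skeleton, measured 16.2, 119 and 83.6 CPM in OA input replicates 1, 2 and 3 and 10.9, 6.82 and 28.7 CPM in the 4E input libraries; SPTB, the beta spectrin of that skeleton, measured 10.3, 130 and 71.6 CPM and 13.0, 20.5 and 19.9 CPM. In the main fit with all libraries none of the 3 passed in 4E input against OA input. Without OA replicate 1 in both fractions ANK1 (edgeR adjusted p = 0.0105), SPTB (0.0105) and HBB (0.0204) were called lower in 4E. Leaving out the OA library with the lowest levels favours such calls. All 3 also passed as lower with no filter, and ANK1 and HBB with the replicate block. The 7 MTRNR2L genes were all higher in 4E heavy (median log2 change 1.36; camera p = 0.0758 with an estimated correlation), and 6 of 7 were higher without OA replicate 1 (median 0.90). The median was 1.32 with median-of-ratios scaling, 1.59 with quantile normalisation and 1.23 without composition scaling. In input all 7 were also higher in 4E (median 0.62), but only 4 of 7 without OA replicate 1 (median 0.023).

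Other splits of the same 6 libraries were refitted to set each count beside chance. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For 4E against OA in input the real split called 3 lists and the highest other 5 (6 of 10 splits gave as many), and in heavy 8 and 7 (1 of 10). For heavy against input, the real split called 51 genes in OA and 70 in 4E, and the highest other split 367 and 0 (2 and 1 of 10 splits gave as many). The OA split with 367 genes set input replicate 1 with heavy replicates 1 and 2 against the rest, which keeps 2 of the 3 same-named pairs together and points to a structure of the OA samples beyond the fraction. Of the splits that part all 3 OA pairs, as the real one does, the 3 others called 0 genes. A real count of 0 is reached by every split, so the splits test nothing for the genes in input and heavy (10 of 10 splits, highest other 0), the lists for heavy against input (10 of 10, highest other 9 in OA and 4 in 4E) and the genes and lists of the interaction (100 of 100, highest other 9 each).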
